A study of Homo sapiens with 18 samples.

How the data were processed

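Chromatin immunoprecipitation sequencing was done on MCF-7 cells treated for 24 h with DMSO, 300 nM GDC-9545 or 300 nM GNE-858, with antibodies against ERα, FOXA1 and H3K27ac. Each of the 9 groups had 2 libraries, 18 in all, and each library came as 1 deposited peak list. Per the submitters' processing notes, GSNAP 2013-10-10, MACS2 2.1.0 and GRCh38 were used, without a stated role for each. Peaks were called per sample against a pooled input after removal of duplicate reads and with a region filter, as far as the names of the deposited lists tell. Drosophila chromatin was added per the labels' protocols, and no scale factor from it was used here. Read counts and depths are not given in the sources used here, so no value rests on depth.

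The ERα and FOXA1 lists have 10 columns in the narrowPeak layout. Their deposited score in column 7, by which the authors' lists are sorted, is a peak strength from a caller not given in the sources used here. Column 9 of these deposited lists holds values read as −log10 of a false discovery rate from their place and range. The deposited H3K27ac lists are MACS2 narrowPeak lists to a p-value of 0.01, with −log10 p-values and q-values. The deposited H3K27ac signal value is a fold enrichment over the input, a ratio. All of these are the authors' own values and were used only to rank or filter peaks within a list. To rank lists on a common scale, each list was taken to the length of the shortest list of its antibody, 299795 peaks for ERα, 299881 for FOXA1 and 64840 for H3K27ac.

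For each antibody, regions were the union of the 20000 strongest peaks of each of its 6 libraries. ERα and FOXA1 peaks were taken as the summit with 100 bp on each side, and H3K27ac peaks as the deposited intervals, and overlapping ones were merged. That gave 29845 ERα, 27983 FOXA1 and 22216 H3K27ac regions, of which 27660.0, 27259 and 21928 had a peak in all 6 lists. Each region's value in a library was −log2 of the rank of its strongest peak in that library's list. Lists were ranked by score for the factors and by −log10 p for H3K27ac, with tied values sharing their mean rank, and a region without a peak was given the common list length. limma 3.58.1 in R 4.3.3 was fitted per antibody to all 6 libraries with a mean per treatment and trended empirical Bayes moderation. The contrasts were GDC-9545 against DMSO, GNE-858 against DMSO and GDC-9545 against GNE-858. A call is a Benjamini-Hochberg adjusted p below 0.05 over all regions of the antibody. Ranks are relative within a library, so a change is a change in order among the regions.

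Regions were assigned to the nearest protein-coding gene with an end within 100 kb, from RefSeq genes on GRCh38 (20056 protein-coding genes). The annotation used has no strand, so distances are to the nearer end of a gene, and a region within 1000 bp of either end is called near a gene end in place of a promoter. The genes named were set by a rule written before the data were examined, as were the main test, the lists and the alternatives. For each antibody, comparison and direction it takes called regions in which both libraries of a group rank above both of the other and the mean rank of the higher group is within 20000, and of these the 10 with the largest change, 1 per nearest gene. It adds the 5 regions strongest in DMSO for each antibody, and the strongest DMSO region of each member of 11 gene lists. Regions picked by their rank in the DMSO libraries are by that choice more prone to fall when compared with those libraries. The text names some regions of each set, not always the largest. Mean ranks are geometric means.

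The lists hold 46 estrogen-induced, 16 estrogen-repressed, 24 luminal lineage, 17 basal and mesenchymal, 23 cell cycle, 19 AP-1 and stress, 13 cholesterol synthesis, 7 aryl hydrocarbon, 13 interferon and 15 housekeeping genes and 15 markers of other cell types. Each list was tested with limma's camera on all regions nearest its genes, with a preset correlation of 0.01 and at least 5 regions, adjusted over the lists and contrasts of an antibody. It was tested again with the correlation estimated from the data.

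Single values per library were compared by exact two-sided permutation tests, whose smallest p is 0.33 for 2 libraries against 2. Sharing between libraries was tested over the 15 partitions of 6 libraries into pairs, one-sided. A factor peak is shared where summits lie within 200 bp, and an H3K27ac peak where intervals overlap by 1 bp. Joint calls were compared across regions with Fisher's exact test, two-sided. Because both compounds are compared with the same DMSO libraries, the relation between their changes was set beside 50 simulations without effects, and computed again with GDC-9545 compared with 1 DMSO library and GNE-858 with the other, both ways, a step chosen after seeing the data. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

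The fits were tested on simulated data with 200 regions changed. A Benjamini-Hochberg cutoff is stricter where fewer regions change. Far more were called in the data, 10354 ERα and 5883 H3K27ac regions for GDC-9545 against DMSO. The shares that follow hold for the simulated setting and do not give the sensitivity of those comparisons. For a log2 change of 2, 55.2% of changed ERα, 46.3% of FOXA1 and 95.5% of H3K27ac regions were called, and for a change of 1 the shares were 6.06%, 1.52% and 77.3%, with 5, 4 and 9 false calls. The alternatives were 10000 or 40000 peaks per library, normal scores in place of log ranks, regions with a peak in all 6 lists alone, peaks within 1000 bp joined, H3K27ac ranked by signal value or compared with an overlap of at least 50% of the shorter interval, false discovery rates of 0.01 and 0.001, 500 bp to a gene end, 20 kb to the nearest gene, an estimated correlation, the replicate number as a term and each library left out in turn. With 20 kb to the nearest gene, a list's regions near gene ends are still compared with all other regions. A change general to regions near gene ends therefore enters that test. With a library left out, the remaining library of its group is assumed to vary as the other groups do. Shares of sites with an estrogen response element had been planned and were not computed, since a genome sequence was not used here.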

Results

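The series holds 18 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from MCF-7 cells, an established estrogen receptor-positive breast cancer line. Cells had been treated for 24 h with DMSO, the solvent, with 300 nM GDC-9545 (giredestrant, an oral estrogen receptor antagonist and degrader) or with 300 nM GNE-858, a compound the labels name by its code. Each treatment was profiled with 3 antibodies: against ERα (the estrogen receptor encoded by ESR1), against FOXA1 (a pioneer transcription factor that opens chromatin for ERα) and against H3K27ac (a histone mark of active enhancers and promoters). Each of the 9 groups had 2 libraries. The deposited peak lists hold no read counts, so the depth of each library is unknown and no interval that needs depth is given. The ERα and FOXA1 lists held 299795 to 299926 peaks each, and the H3K27ac lists 64840 to 71755. Values below are ranks of a region within each library's own list, rank 1 being the strongest peak. A change is the difference in −log2(rank), given ± its standard error with n = 2 libraries per group, so that a positive change means that the region moved toward the top. A gain or loss shared by all regions leaves ranks as they are and cannot be seen this way. A region without a peak in a list was given the common list length of its antibody, which limits how large its change can be. Where both libraries of a group lack a peak in the window, they get the same value. That adds no spread, and the change can be large though a peak lies nearby. The limma p-values of single regions and the exact permutation and partition p-values rest on the spread between these libraries. The labels do not say whether the 2 libraries of a group came from separate cultures. Fisher's exact tests and the set tests of gene lists compare regions with regions, which are not independent replicates.

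Fewer ERα peaks passed the caller's false discovery rate of 0.01 after GDC-9545 and more passed after GNE-858. The mean was 82607.5 ± 1026 (SD, n = 2) with DMSO, 52040.5 ± 7946 with GDC-9545 and 110243 ± 3130 with GNE-858. That is 0.630 times DMSO with GDC-9545 and 1.33 times DMSO with GNE-858. For FOXA1 the means were 94005 ± 610 with DMSO, 98684.5 ± 1098 with GDC-9545 and 92160.0 ± 820 with GNE-858, and for H3K27ac they were 61021 ± 1690, 60214 ± 3468 and 62488.5 ± 698 in the same order. With 2 libraries against 2, the exact two-sided permutation test cannot give a p below 0.33, which is the value for both ERα comparisons with DMSO. The number of peaks past a false discovery rate also moves with read depth, which is unknown.

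**Figure D1:**
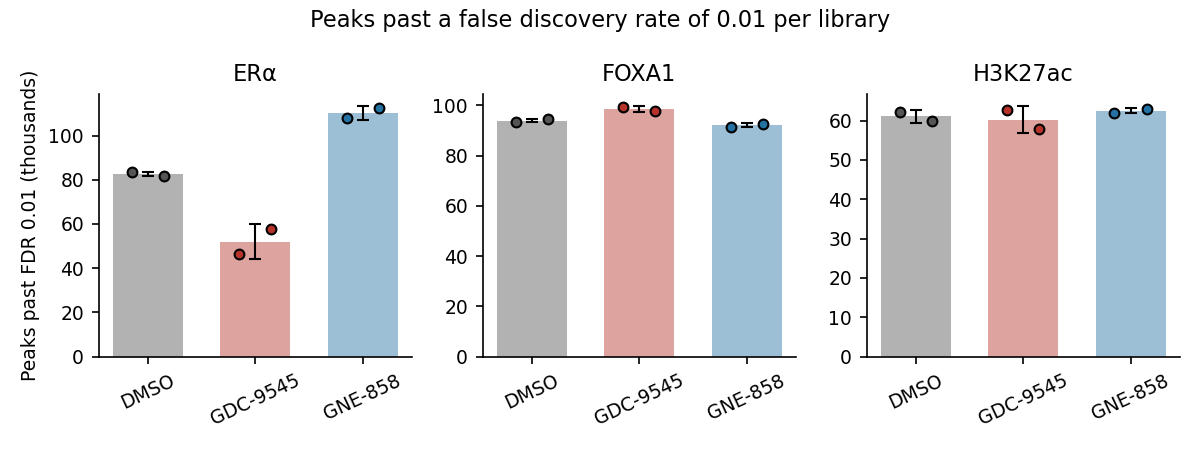
Peaks (in units of 1000) past a false discovery rate of 0.01 in each library (points), with the mean (bar) and SD (error bar) of the 2 libraries per treatment, for each antibody. The ERα bars differ between treatments, from 52040.5 peaks on average with GDC-9545 to 110243 with GNE-858.

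GDC-9545 against DMSO asks how the degrader changed the places where ERα was bound. ERα rank fell at many of the strongest sites in DMSO. The region near NXNL2 (chromosome 9, 88530079 to 88530507, GRCh38) went from a mean rank of 11 with DMSO to 1330.2 with GDC-9545, a change of −6.92 ± 1.10 (adjusted p = 0.00204, limma). Regions in or near YIPF5 (−6.32 ± 0.50), TMEM229B (−6.05 ± 1.5), PEBP4 (−5.80 ± 1.45), PLAC1 (−5.61 ± 0.29), IL24 (−5.57 ± 0.51) and SCNN1B (−5.45 ± 0.70) also fell. Regions near METRNL (7.41 ± 0.28), BOD1 (5.53 ± 0.48), GSTZ1 (5.06 ± 1.27), IRF2BPL (4.98 ± 0.96) and TMOD3 (4.82 ± 1.05) rose. Those near METRNL, IRF2BPL and TMOD3 had no DMSO peak. Across 29845 regions, 5998 fell and 4356 rose, with median changes of −1.64 and 1.45.

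Of 44 estrogen-induced genes with an ERα region, the strongest DMSO region of 26 fell with GDC-9545 and that of 1 rose (28 and 1 adjusted over the list alone). Here and in all counts by gene against DMSO below, the region was picked in the same DMSO libraries, which favours falls. The set tests use all regions of a list. The falls included PGR, the progesterone receptor gene (mean rank 418 with DMSO and 3401 with GDC-9545, −3.02 ± 0.26), RERG (−5.14 ± 0.47), SIAH2, a ubiquitin ligase gene (−4.44 ± 0.76), CA12, a carbonic anhydrase gene (−4.40 ± 0.66), RBBP8 (−3.65 ± 0.26), PRSS23 (−3.23 ± 0.24) and CCND1, the cyclin D1 gene (−2.21 ± 0.31). CDC6, a DNA replication licensing gene, was the member that rose (1.5 ± 0.33). The GREB1 region went from a mean rank of 17.6 to 164, a change of −3.22 ± 1.11 that just missed the threshold (adjusted p = 0.0514). It passed with 10000 peaks per library (adjusted p = 0.0261), over regions with a peak in all 6 lists (0.0202) and with peaks within 1000 bp joined (0.0326). No call was made at TFF1 (−0.29 ± 0.35), MYC (0.63 ± 0.45), XBP1 (0.09 ± 0.52), RARA (0.03 ± 0.44), ESR1 (1.30 ± 0.56) or FOXA1 (0.07 ± 0.25). ESR1 rose without GDC-9545 replicate 2 (2.18, adjusted p = 0.0125). All regions of the list, as a set, had more negative changes than other regions (camera, adjusted p = 6.11e-06, and 0.0734 with an estimated correlation).

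None of the other 10 lists passed the set test in this comparison with the main settings (adjusted p from 0.0504 to 0.573). The cell cycle list, at 0.0504 and upward, passed with the replicate number as a term (adjusted p = 0.0424), with gene ends within 20 kb (0.0186) and without DMSO replicate 2, GDC-9545 replicate 1 or GNE-858 replicate 2 (0.0372, 0.0355 and 0.0458). The 20 kb test compares regions near gene ends with all others, and ERα regions near gene ends rose more often in general, as given below. Of 22 luminal lineage genes, 3 fell and 2 rose (3 and 2 adjusted over the list alone). GATA3, a luminal transcription factor gene (−2.34 ± 0.35), MLPH (−2.97 ± 0.53) and AR (−0.85 ± 0.22) fell, and KRT18, a luminal keratin gene (4.20 ± 0.75), and ERBB3 (1.28 ± 0.27) rose. Of 16 estrogen-repressed genes, KLF6 (−2.75 ± 0.21), KRT13 (−2.32 ± 0.29) and NDRG1 (−1.41 ± 0.24) fell (4 genes adjusted over the list alone), and 3 rose (3 adjusted over the list alone), among them CCNG2, a cyclin G gene (0.94 ± 0.25). Of 12 cell cycle genes 3 rose and 2 fell (7 and 2 adjusted over the list alone). Of 15 AP-1 and stress genes 3 rose and 5 fell (3 and 5 adjusted over the list alone). The luminal genes had a median change of 0.08 over their strongest DMSO regions and −0.30 over all their regions, and the estrogen-repressed genes a median of 0.30 and a mean of −0.18 over their strongest regions. Leaving out 1 library moved the ERα count furthest for DMSO, from 10354 regions to 3456 without DMSO replicate 1 and to 4036 without DMSO replicate 2. Of the 29 called regions named for this comparison, 8 lost the call without some library (adjusted p 0.0526 to 0.237): TMEM229B (without DMSO replicate 2, either GDC-9545 library or GNE-858 replicate 2), PEBP4 (without any 1 GDC-9545 or GNE-858 library), GSTZ1 (without any 1 GNE-858 library), KRT18 (without DMSO replicate 1), AR, ERBB3 and CDC6 (without any 1 DMSO library) and CCNG2 (without any 1 DMSO or GNE-858 library). With 40000 peaks per library TMEM229B missed the threshold (adjusted p = 0.0567), and on normal scores PEBP4, GSTZ1 and IRF2BPL did (adjusted p 0.0528 to 0.178). The TMOD3 region turned to −1.05 (adjusted p = 0.0131) when peaks within 1000 bp were joined.

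The regions that rose and those that fell with GDC-9545 lay in different places. Of the 4356 that rose, 1428 (32.8%) were within 1000 bp of an end of a protein-coding gene, against 8.31% of regions not called, an odds ratio of 5.38. Of the 5998 that fell, 116 (1.93%) were, an odds ratio of 0.218 (Fisher's exact test across regions, two-sided, p = 9.42e-83). Regions are not independent replicates, so this p holds for these lists alone. Among the 20000 strongest ERα peaks of each library, the share near a gene end was 7.59% ± 0.41 (SD, n = 2) with DMSO, 13.3% ± 1.9 with GDC-9545 and 6.19% ± 0.13 with GNE-858. The differences from DMSO were 5.69 points with GDC-9545 and −1.41 points with GNE-858, each with an exact permutation p of 0.33.

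**Figure D2:**
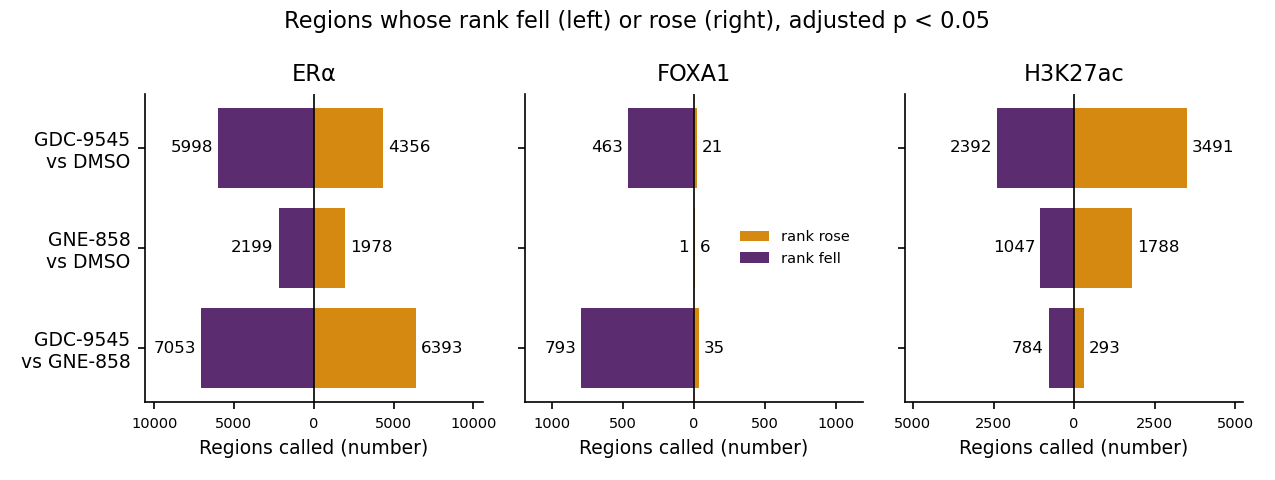
Number of regions whose rank fell (left of 0) or rose (right of 0) at an adjusted p below 0.05, for each antibody and comparison, each panel with its own scale. ERα and H3K27ac moved both ways, and the FOXA1 regions called with GDC-9545 mostly fell, at 463 against 21 that rose. The number and balance of the FOXA1 calls depended on the pooled spread, which the GNE-858 libraries enter.

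GNE-858 against DMSO asks the same of the second compound, and here ERα gained rank at a set of weak DMSO sites. The region near MINDY4B (chromosome 3, 150844565 to 150845019) went from a mean rank of 8247 to 107 (6.26 ± 0.25, adjusted p = 5.13e-05), and regions in IGSF5 (5.96 ± 0.56), near METRNL (5.94 ± 0.28), near GPR139 (5.31 ± 0.94), in GAB2 nearest USP35 (5.30 ± 0.72), near GPAM (5.24 ± 0.46), in TGM2, a transglutaminase gene (5.05 ± 0.24), and in RPS6KL1 (5.0 ± 0.26) rose too. The region near MMP17, a metalloproteinase gene, fell from a mean rank of 14.4 to 342 (−4.57 ± 0.78). Regions in BFSP2 (−6.12 ± 0.41), near COX6C (−5.67 ± 0.29) and in RASIP1 (−5.29 ± 0.97) had no GNE-858 peak within their windows. When peaks within 1000 bp were joined, those 3 changes turned to 0.33, 0.62 and 0.07, and the rises near METRNL and GPR139 ended (adjusted p = 0.477 and 0.869). Across the 29845 regions, 2199 fell and 1978 rose, with median changes of −1.28 and 1.39. Of the regions that rose, 4.10% were near a gene end, against 10.8% of those not called (odds ratio 0.351, p = 6.20e-26, Fisher's exact test), and of those that fell, 13.7% (odds ratio 1.31, p = 7.10e-05).

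The estrogen-induced genes went both ways with GNE-858. Of 44 with an ERα region, 9 fell and 3 rose (13 and 4 adjusted over the list alone), and the set test, downward, missed the threshold (adjusted p = 0.0504; adjusted p = 0.170 with an estimated correlation). It passed with the replicate number as a term (adjusted p = 0.0424), with gene ends within 20 kb (0.00609) and without GDC-9545 replicate 1 or 2 (0.0355 and 0.0469). CA12 (−3.18 ± 0.66), TPD52L1 (−1.89 ± 0.49) and CCN5 (−1.71 ± 0.41) fell, and SGK3, a kinase gene (2.00 ± 0.41), HSPB8, a small heat shock protein gene (1.27 ± 0.36), and ELOVL2, a fatty acid elongase gene (1.20 ± 0.21), rose. No call was made at TFF1 (0.60 ± 0.35), GREB1 (−0.31 ± 1.11), PGR (−0.72 ± 0.26), CCND1 (0.02 ± 0.31), MYC (−0.09 ± 0.45), XBP1 (−1.32 ± 0.52), RARA (−0.87 ± 0.44), ESR1 (−0.13 ± 0.56), FOXA1 (−0.80 ± 0.25) or GATA3 (0.87 ± 0.35). The FOXA1 change passed with 10000 peaks per library (adjusted p = 0.0399), over regions with a peak in all 6 lists (0.0471) and without GDC-9545 replicate 1 or 2 (0.0296 and 0.0295). Calls for CA12, TPD52L1, CCN5 and HSPB8 were lost with 40000 peaks per library, and those and SGK3 on normal scores (adjusted p 0.0545 to 0.122 over these and KRT19).

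Luminal lineage genes ranked lower with GNE-858 as a list (adjusted p = 0.00826; adjusted p = 0.516 with an estimated correlation). Of 22, 4 fell and 0 rose (5 and 1 adjusted over the list alone): ELF3, an epithelial transcription factor gene (−2.22 ± 0.28), KRT19, a luminal keratin gene (−1.90 ± 0.54), CLDN4, a tight junction gene (−1.44 ± 0.29), and SPDEF (−1.01 ± 0.21). The AP-1 and stress list also ranked lower (adjusted p = 0.0430; adjusted p = 0.502 with an estimated correlation), but not without DMSO replicate 1 or GNE-858 replicate 1 (0.117 and 0.0826). Of its 15 genes, JUNB (−2.37 ± 0.22), GADD45B (−2.0 ± 0.44), DUSP5 (−1.94 ± 0.25) and IER2 (−1.45 ± 0.28) fell, and KLF4 (1.61 ± 0.23) and ATF3 (1.44 ± 0.22) rose, which makes 4 and 2 (5 and 3 adjusted over the list alone). Of 16 estrogen-repressed genes, 5 fell and 2 rose (6 and 3 adjusted over the list alone), with GPER1 (−2.10 ± 0.25) falling and NDRG1 (1.63 ± 0.24) and KLF6 (1.46 ± 0.21) rising. The 9 lists that did not pass had adjusted p from 0.0504 to 0.862, and the estrogen-repressed list passed downward with gene ends within 20 kb (0.0499).

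The ERα calls for GNE-858 rested on all 4 libraries compared and changed with the spread of the others. The count of 4177 regions went to 51 (8 lower, 43 higher) without DMSO replicate 1, 70 (19 and 51) without DMSO replicate 2, 55 (15 and 40) without GNE-858 replicate 1 and 20 (3 and 17) without GNE-858 replicate 2, and to 9828 and 9834 without GDC-9545 replicate 1 or 2. Of the 31 called regions named, only those at MINDY4B, METRNL, TGM2, RPS6KL1, BFSP2 and COX6C kept the call whichever library was left out, and the other 25 lost it in some case (adjusted p 0.0502 to 0.292). Of those that kept it, METRNL lost the call and BFSP2 and COX6C turned over when peaks within 1000 bp were joined, as given above. KRT19 also lost its call with the replicate number as a term (adjusted p = 0.0577). With 40000 peaks per library, 2213 regions were called, and 2646 on normal scores.

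Set directly against each other, GDC-9545 and GNE-858 at the same dose and time differed at more ERα regions than either did from DMSO, with 7053 lower and 6393 higher after GDC-9545. B3GALT5 (−8.06 ± 0.31), CD276, an immune checkpoint gene (−7.79 ± 0.46), IGSF5 (−7.36 ± 0.56) and PREX1 (−7.22 ± 1.03) had the largest falls. RNF41 (5.88 ± 0.59), TNK2 (5.55 ± 1.21), DERL1 (5.42 ± 0.58) and HIKESHI (5.25 ± 0.96) were among the largest rises. The COX6C region, at 6.55 ± 0.29, turned to −0.01 (adjusted p = 0.980) when peaks within 1000 bp were joined. Of 44 estrogen-induced genes, 18 ranked lower with GDC-9545 and 3 higher (18 and 4 adjusted over the list alone). These included HSPB8 (−4.18 ± 0.36), RBBP8 (−3.88 ± 0.26), RERG (−3.63 ± 0.47), ELOVL2 (−3.47 ± 0.21), PGR (−2.31 ± 0.26) and CCND1 (−2.23 ± 0.31) on the lower side, and CDC6 (2.63 ± 0.33) and SLC7A5, an amino acid transporter gene (1.62 ± 0.26), on the higher. The set test gave an adjusted p of 0.0347 (adjusted p = 0.170 with an estimated correlation), and it did not pass with gene ends within 20 kb (0.399) or without GDC-9545 replicate 1 (0.0780). KLF6 of the estrogen-repressed list differed by −4.22 ± 0.21, and in that list 3 were lower and 8 higher (3 and 8 adjusted over the list alone), a set test past no threshold, as for all 10 other lists (adjusted p from 0.0644 to 0.772). Of all ERα regions higher with GDC-9545 than with GNE-858, 30.0% were within 1000 bp of a gene end, against 6.59% of those not called. An upward shift with gene ends within 20 kb therefore need not be particular to a list. With gene ends within 20 kb the cell cycle (adjusted p = 0.0177), estrogen-repressed (0.0177) and luminal (0.0186) lists passed upward, and the cell cycle list also without GDC-9545 replicate 1 or GNE-858 replicate 2 (0.0355 and 0.0458). The count of 13446 regions fell to 7415 without GNE-858 replicate 1 and 6540 without GNE-858 replicate 2, the last below the 7047 then called for GDC-9545 against DMSO, and the calls at TNK2 (both) and HIKESHI (replicate 2) were lost there (adjusted p 0.0634 to 0.0700). On normal scores TNK2 had an adjusted p of 0.0564.

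The opposite calls can be counted region by region. Both comparisons take a region's spread from the same fit, so a region with a small spread is called more easily for both, in any direction. Independent calls are therefore not a full baseline. The excess over them, found below in every pair of directions, does not by itself show opposite changes. Of the ERα regions called for both compounds, 460 rose with GDC-9545 and fell with GNE-858, and 519 fell with GDC-9545 and rose with GNE-858, where independent calls would give 321.0 and 397.5. In the same direction, 596 fell with both and 367 rose with both, where independent calls would give 441.9 and 288.7. Simulations with shared controls and no effects gave 0.1 calls shared in any direction on average. Without effects almost no region is called, so that number cannot show what shared controls do among many calls. Both comparisons use the same DMSO libraries, which alone give a correlation of 0.50 between the changes in those 50 simulations, and the correlation found was −0.00255, with a covariance of −0.00284 against 0.0977. With a separate DMSO library for each compound, the correlation was −0.0879 (GDC-9545 with DMSO replicate 1) and −0.0288 (GDC-9545 with DMSO replicate 2), and the covariance −0.107 and −0.0333.

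Fewer of the strongest ERα sites had a FOXA1 peak with either compound than with DMSO. With DMSO, 56.2% ± 0.23 (SD, n = 2) of the 20000 strongest ERα peaks had a FOXA1 peak of the same treatment, against 47.4% ± 3.3 with GDC-9545 and 51.0% ± 1.2 with GNE-858. The differences were −8.78 and −5.16 points (exact permutation p = 0.33 each, the smallest possible), and −6.37 and −2.15 points when the DMSO FOXA1 peaks were used throughout, the second with GNE-858 at 54.0% ± 1.6. The FOXA1 peaks found in both libraries numbered 17978 with DMSO, 17665 with GDC-9545 and 15522 with GNE-858, a set that includes the library that stood apart from the other FOXA1 libraries, GNE-858 replicate 1. On average over pairs, libraries of a group shared more of their 20000 strongest peaks than libraries of different groups did, by 12.2 points for ERα, 3.88 for FOXA1 and 3.57 for H3K27ac. Each had a one-sided exact p of 0.0667, the smallest that 15 partitions allow. For FOXA1 this did not hold within GNE-858, whose libraries shared 77.5%, less than the mean of 81.9% ± 4.9 (SD over 4 pairs) between DMSO and GNE-858 and of 79.6% ± 5.6 between the compounds. The FOXA1 difference was between 1.93 points (without GDC-9545 replicate 2) and 9.72 points (without GNE-858 replicate 2), and stood at 2.09 and 2.05 without DMSO replicate 1 or 2 and at 2.26 without GDC-9545 replicate 1. For ERα, DMSO libraries shared 74.6% ± 1.6 (SD over 4 pairs) with GDC-9545 libraries and 79.9% ± 0.96 with GNE-858 libraries, against 89.8% within DMSO, 82.1% within GDC-9545 and 89.8% within GNE-858.

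FOXA1, the partner factor, was called lower with GDC-9545 at sites that included estrogen-regulated genes. How many sites were called, and how many of them rose, depended on the libraries in the pooled spread, as given below. The region in GREB1, an early estrogen target (chromosome 2, 11532436 to 11532651), went from a mean rank of 2150.3 to 73927 (−5.10 ± 0.35, adjusted p = 2.39e-04). Regions in BMPER (−5.59 ± 0.42), near NECAB1 (−5.52 ± 0.44), CPXM2 (−5.34 ± 0.34), TRPC6, a calcium channel gene (−5.10 ± 0.54), NXNL2 (−4.83 ± 0.40) and CDH26, a cadherin gene (−4.76 ± 0.44), fell. Regions near SDC4 (2.42 ± 0.42), MBIP (2.31 ± 0.49), in PIK3AP1 (2.12 ± 0.44) and in IL1R1 (2.07 ± 0.41) rose. Of 27983 regions 463 fell and 21 rose. Of 41 estrogen-induced genes, 8 fell and 0 rose (17 and 0 adjusted over the list alone), a list shift with adjusted p = 3.55e-12 (adjusted p = 0.722 with an estimated correlation). The strongest DMSO region of GREB1 was another, which fell by 2.99 ± 0.52. The other falls were at SIAH2 (−3.88 ± 0.44), PDZK1 (−3.48 ± 0.44), PGR (−3.03 ± 0.42), KCNK15 (−3.03 ± 0.39), ELOVL2 (−2.98 ± 0.39), AMZ1 (−2.62 ± 0.43) and PKIB (−1.87 ± 0.37). No call was made at TFF1 (−1.25 ± 0.52), CCND1 (0.32 ± 0.66), MYC (−0.78 ± 0.55), XBP1 (−1.50 ± 0.68), RARA (−1.88 ± 0.47), ESR1 (0.00 ± 0.81), FOXA1 (−0.71 ± 0.46) or GATA3 (0.05 ± 0.65). The other 10 lists had adjusted p from 0.259 to 0.993, and the luminal list passed downward with gene ends within 20 kb (0.0341). Fewer of the regions that fell were near a gene end, 2.38% against 6.84% of those not called (odds ratio 0.331, p = 3.29e-05, Fisher's exact test).

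The FOXA1 library of GNE-858 replicate 1 stood apart from the other FOXA1 libraries. Across regions its Spearman correlation with them was 0.597 to 0.691, against 0.789 to 0.932 among the other 5, and 8.21% of its strongest peaks were near a gene end, against 4.73% in replicate 2. The share near a gene end averaged 4.85% ± 0.27 with DMSO, 5.26% ± 0.44 with GDC-9545 and 6.47% ± 2.5 with GNE-858 (exact permutation p = 0.667 for either compound), and the GNE-858 difference of 1.62 points was −0.12 without replicate 1 and 3.36 without replicate 2. The GDC-9545 difference of 0.405 points was 0.715 and 0.0950 without GDC-9545 replicate 1 or 2, and 0.215 without DMSO replicate 1. That library enters the pooled spread of all FOXA1 comparisons. Without it the GDC-9545 count went from 484 to 3810 (2383 lower, 1427 higher), and without replicate 2 to 3751. The count was 67 and 82 without DMSO replicate 1 or 2, and 182 and 105 without GDC-9545 replicate 1 or 2. Of the 18 called regions named, those at BMPER, NECAB1, CPXM2, GREB1, TRPC6, NXNL2, CDH26 and SIAH2 kept the call whichever library was left out, and the other 10 lost it without a DMSO or GDC-9545 library (adjusted p 0.0504 to 0.572). TFF1 (adjusted p = 0.0439 and 0.0481) and RARA (0.00331 and 0.00364) passed without GNE-858 replicate 1 or 2. On normal scores CPXM2, TRPC6, MBIP and PIK3AP1 did not pass (adjusted p 0.0554 to 0.264), nor did MBIP with 40000 peaks per library (0.0520).

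With GNE-858, FOXA1 was called higher at 6 regions and lower at 1, and no gene of any list passed. The rises had nearest genes ZNF706 (mean rank 25363 to 597, 5.41 ± 0.49, adjusted p = 0.00508), FGF3, a fibroblast growth factor gene (4.38 ± 0.55), TSKU (4.17 ± 0.52), NR5A2, a nuclear receptor gene (3.86 ± 0.43), and PRKCH (2.76 ± 0.35), and the fall was in GAB2 nearest USP35 (−4.49 ± 0.56). When peaks within 1000 bp were joined the USP35 change turned to 3.92 (adjusted p = 0.0157) and 13 regions were called. At an unadjusted p below 0.05 there were 2749 regions, and on normal scores 0 regions passed, these 6 at adjusted p 0.204 to 0.459. With 40000 peaks per library PRKCH missed the threshold (adjusted p = 0.0512). The count was 1 and 0 without DMSO replicate 1 or 2, 2 without either GDC-9545 library, 68 without GNE-858 replicate 1 (20 lower, 48 higher) and 8590 without GNE-858 replicate 2 (5533 lower, 3057 higher), and every region named lost its call without DMSO replicate 2, all but ZNF706 also without DMSO replicate 1 or a GDC-9545 library (adjusted p 0.0790 to 1.00 over these). None of the 11 lists passed (adjusted p from 0.148 to 0.956). Without GNE-858 replicate 2 the AP-1 and stress (0.00587), estrogen-repressed (0.0161) and luminal (0.0219) lists passed upward, and with gene ends within 20 kb the estrogen-repressed list (0.0341). Of 41 estrogen-induced genes, 0 rose or fell (5 rose adjusted over the list alone).

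Against each other, FOXA1 ranked lower with GDC-9545 than with GNE-858 at 793 regions and higher at 35. Lower regions lay near NR5A2 (−7.20 ± 0.43), IER3 (−6.98 ± 0.76), TSKU (−6.83 ± 0.52), ZNF706 (−6.79 ± 0.49) and CDH26 (−6.67 ± 0.44), and the largest rise lay near CUX2 (5.52 ± 1.23). Of 41 estrogen-induced genes, 12 were lower and 0 higher (19 and 0 adjusted over the list alone), among them PDZK1 (−4.99 ± 0.44), KCNK15 (−4.90 ± 0.39) and IGFBP4, an insulin-like growth factor binding protein gene (−4.45 ± 0.51). The list shift had an adjusted p of 1.54e-10 (adjusted p = 0.722 with an estimated correlation), and the 10 other lists had adjusted p from 0.0646 to 0.956. The AP-1 and stress list, at 0.0646, passed downward with the replicate number as a term (0.0411), with gene ends within 20 kb (0.0341) and without GDC-9545 replicate 2 or GNE-858 replicate 2 (0.0235 and 0.00128). The luminal list passed downward with gene ends within 20 kb (0.00585) and without GNE-858 replicate 2 (0.00342). The count of 828 was 1298 without GNE-858 replicate 1, the library that stood apart, 10747 (4327 lower, 6420 higher) without GNE-858 replicate 2, 536 and 532 without DMSO replicate 1 or 2, and 474 and 392 without GDC-9545 replicate 1 or 2. CUX2 lost its call without either GDC-9545 library (adjusted p 0.767 and 0.839), with 10000 peaks per library (0.0642), on normal scores (0.204), with a replicate term (0.0517) and with peaks within 1000 bp joined (0.824), and IER3 on normal scores (0.239).

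**Figure D3:**
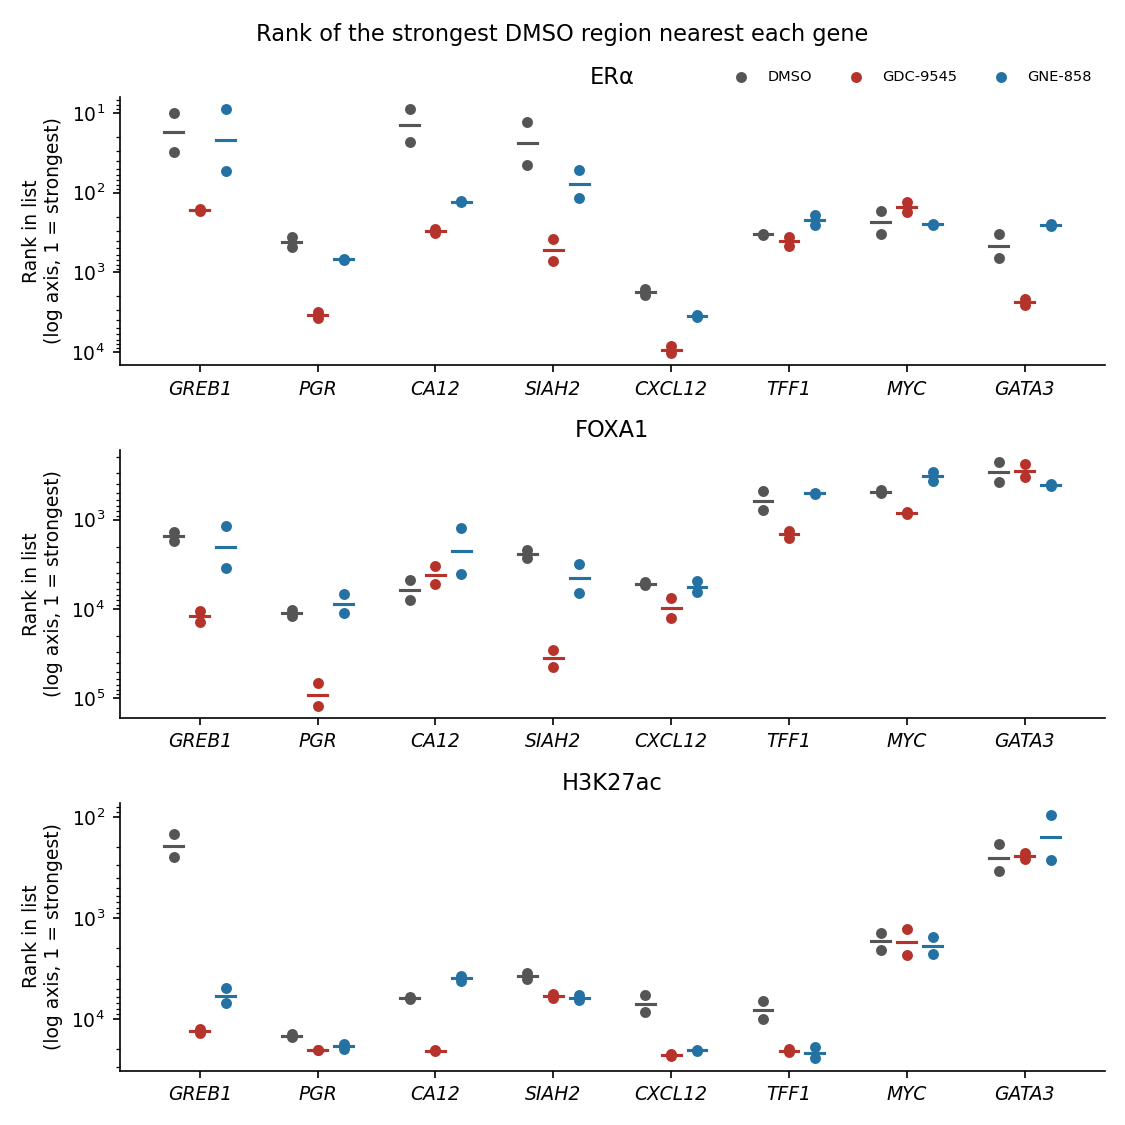
Rank (log axis, 1 at the top is the strongest peak) of the strongest DMSO region nearest each of 8 estrogen-induced or luminal genes in each library (points), with the geometric mean of the 2 libraries (line). With GDC-9545 the GREB1 region went from a mean rank of 17.6 to 164 for ERα and from 193 to 13203 for H3K27ac.

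H3K27ac, the mark of active enhancers, fell with GDC-9545 at estrogen-regulated genes and at cell cycle genes. The region in GREB1 (chromosome 2, 11538966 to 11552755) went from a mean rank of 193 to 13203 (−6.10 ± 0.34, adjusted p = 2.14e-10), and that near VXN from 27.3 to 7530.3 (−8.11 ± 0.54). Regions near C8orf34 (−7.32 ± 0.82), CD180 (−6.20 ± 0.77), THBS1, the thrombospondin 1 gene (−5.84 ± 0.22), and CDH26 (−5.59 ± 0.25) also fell. Regions near ZNF157 (4.35 ± 0.56), MFSD1 (4.31 ± 0.57), DYSF (4.08 ± 0.65), in ZNF444 (3.98 ± 0.78) and in CDK17 (3.56 ± 0.64) rose. Of 22216 regions, 2392 fell and 3491 rose, with median changes of −0.83 and 0.71. Of 43 estrogen-induced genes, 31 fell and 0 rose (35 and 0 adjusted over the list alone), with adjusted p = 2.67e-29 for the list (adjusted p = 0.191 with an estimated correlation). They included STC2 (−2.96 ± 0.44), AMZ1 (−2.46 ± 0.21), NOS1AP (−2.36 ± 0.23), TPD52L1 (−2.32 ± 0.39), MYB (−2.15 ± 0.16), CA12 (−1.73 ± 0.17), CXCL12, a chemokine gene (−1.70 ± 0.16), TFF1, the trefoil factor 1 gene (−1.33 ± 0.17), and PGR (−0.46 ± 0.14).

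Of 20 cell cycle genes, 12 fell in H3K27ac rank with GDC-9545 and 0 rose (14 and 1 adjusted over the list alone; list adjusted p = 3.87e-05, adjusted p = 0.295 with an estimated correlation). MCM4 (−1.57 ± 0.31) and MCM2 (−1.13 ± 0.17) of the replicative helicase, TYMS, the thymidylate synthase gene (−1.36 ± 0.29), and PCNA, the sliding clamp gene (−1.14 ± 0.22), were among them. Of 16 estrogen-repressed genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone): BIK, a cell death gene (1.79 ± 0.20), CCNG2 (1.51 ± 0.33), PSCA (0.76 ± 0.20) and BLNK (0.66 ± 0.15). That list had an adjusted p of 0.010 (adjusted p = 0.390 with an estimated correlation; 0.0528 without GDC-9545 replicate 1). Of 8 interferon genes, 1 rose, OAS1 (0.61 ± 0.15), and 0 fell (1 and 0 adjusted over the list alone), with 7 of the list's 16 regions rising (list adjusted p = 0.010, adjusted p = 0.477 with an estimated correlation, and 0.0528 without GDC-9545 replicate 1). Of 24 luminal genes, 5 fell (5 adjusted over the list alone): KRT19 (−3.59 ± 0.78), ESR1 (−2.91 ± 0.69), KRT8 (−2.62 ± 0.72), ELF3 (−1.62 ± 0.55) and AGR2 (−0.43 ± 0.13). The luminal list did not pass (adjusted p = 0.108) except, downward, with gene ends within 20 kb (0.0214), and the 6 lists that did not had adjusted p from 0.0663 to 0.663. The AP-1 and stress list, at 0.0663, passed downward without DMSO replicate 1 or GNE-858 replicate 1 (0.0420 and 0.0460). No call was made at MYC (−0.04 ± 0.40), CCND1 (−0.77 ± 1.02), XBP1 (−0.83 ± 1.21), RARA (−0.84 ± 0.33), FOXA1 (−1.61 ± 0.70) or GATA3 (0.06 ± 0.81). RARA passed without GNE-858 replicate 2 (adjusted p = 0.0399), and RARA and FOXA1 with a replicate term in which the GDC-9545 numbers were crossed (0.0351 and 0.0463).

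Regions that rose or fell in H3K27ac with GDC-9545 lay away from gene ends, at 11.4% and 24.9% against 48.0% of regions not called (odds ratio for those that fell 0.360, p = 2.62e-104, Fisher's exact test). Among the 20000 strongest H3K27ac peaks, 48.5% ± 1.3 (SD, n = 2) were near a gene end with DMSO, 46.5% ± 0.060 with GDC-9545 and 47.1% ± 0.40 with GNE-858. The differences from DMSO were −2.07 and −1.47 points (exact permutation p = 0.33 each), −1.16 and −0.560 points without DMSO replicate 1, and −2.98 and −2.38 points without DMSO replicate 2. The count of 5883 regions was 3889 without DMSO replicate 1, 2356 with 10000 peaks per library and 3087 with the lists ranked by signal value. Of the 34 called regions named, 9 lost the call without some library (adjusted p 0.0501 to 0.520): ZNF444, PGR, PSCA, BLNK, ELF3 and AGR2 without DMSO replicate 1; CCNG2, KRT8, ELF3 and AGR2 without DMSO replicate 2; PGR, OAS1 and AGR2 without GDC-9545 replicate 1; PGR, PSCA, KRT8, ELF3 and AGR2 without GDC-9545 replicate 2; and ELF3 without GNE-858 replicate 1. Ranked by signal value, DYSF, ZNF444, PGR, MCM4, PCNA, CCNG2, PSCA, KRT19, ESR1 and ELF3 did not pass (adjusted p 0.0562 to 0.338). ELF3 also missed under 4 further settings and AGR2 with 40000 peaks per library (adjusted p 0.0511 to 0.0913).

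With GNE-858, H3K27ac fell at many of the same genes. GREB1 went from a mean rank of 193 to 5859 (−4.93 ± 0.34, adjusted p = 3.65e-08), and the regions near VXN (−5.70 ± 0.54), C8orf34 (−5.15 ± 0.82), KRT18 (−5.12 ± 1.58) and COX6C (−4.50 ± 0.42) fell. Regions in FUT9, a fucosyltransferase gene (3.97 ± 0.50), nearest LTBR (3.34 ± 0.95), in MSL2 (3.30 ± 0.97), near ARL8A (3.2 ± 0.37) and in CDK17 (3.18 ± 0.64) rose. Across regions 1047 fell and 1788 rose, with median changes of −0.75 and 0.70. Of 43 estrogen-induced genes, 20 fell and 1 rose (22 and 1 adjusted over the list alone), with adjusted p = 2.32e-20 for the list (adjusted p = 0.191 with an estimated correlation). STC2 (−2.18 ± 0.44), NOS1AP (−1.82 ± 0.23), CXCL12 (−1.53 ± 0.16) and TFF1 (−1.40 ± 0.17) fell and CA12 rose (0.66 ± 0.17), while PGR (−0.35 ± 0.14) and ESR1 (−2.10 ± 0.69) did not pass, though ESR1 did with the crossed replicate term (adjusted p = 0.0266). Of 20 cell cycle genes, 9 fell and 0 rose (11 and 0 adjusted over the list alone), such as PCNA (−1.10 ± 0.22), MCM4 (−0.96 ± 0.31) and CDK1 (−0.88 ± 0.19), with adjusted p = 8.70e-07 for the list (adjusted p = 0.246 with an estimated correlation). Of 16 estrogen-repressed genes 1 rose, BIK (1.40 ± 0.20), and 0 fell (1 and 0 adjusted over the list alone; list adjusted p = 0.0162, adjusted p = 0.397 with an estimated correlation, and 0.0554 without GNE-858 replicate 2). Of 24 luminal genes CLDN4 rose (2.70 ± 0.64) and KRT18 and ELF3 (−2.40 ± 0.55) fell, 1 and 2 (1 and 3 adjusted over the list alone), and that list was among the 7 that did not pass (adjusted p from 0.149 to 0.959). The aryl hydrocarbon list passed upward without GNE-858 replicate 1 (0.0395).

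The H3K27ac calls for GNE-858 depended more on single libraries and on the score used to rank. The count of 2835 was 1130.0 without DMSO replicate 1 (573 lower, 557 higher), 1396 without DMSO replicate 2, 1140.0 without GNE-858 replicate 1 and 1322 without GNE-858 replicate 2. It was 1206 with 10000 peaks per library, 1715 on normal scores and 402 (200 lower, 202 higher) when ranked by signal value. Of the 21 called regions named, those at VXN, C8orf34, GREB1, COX6C, FUT9, ARL8A, NOS1AP, CXCL12, TFF1 and BIK kept the call whichever library was left out, and the other 11 lost it in some case (adjusted p 0.0511 to 0.475). Ranked by signal value, 15 of the 21 did not pass (adjusted p 0.0517 to 0.827), GREB1, COX6C, FUT9, NOS1AP, CXCL12 and BIK being those that did. NOS1AP lost its call on normal scores, as did KRT18, LTBR and MSL2 (adjusted p 0.122 to 0.576). The last 3 also lost it with 40000 peaks per library (0.131 to 0.227), KRT18 and MCM4 with 10000 (0.0519 to 0.0616), and MCM4 with a replicate term (0.0655).

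Between the compounds, H3K27ac ranked lower with GDC-9545 than with GNE-858 at 784 regions and higher at 293. Regions near CD180 (−6.76 ± 0.77), NAIF1 (−5.20 ± 0.23), CDH26 (−5.19 ± 0.25) and ARL8A (−4.89 ± 0.37) were lower, and regions near BAK1, a cell death gene (2.48 ± 0.42), FIRRM (2.28 ± 0.46) and MYO6 (2.25 ± 0.43) higher. Of 43 estrogen-induced genes 10 were lower and 0 higher (15 and 0 adjusted over the list alone), with AMZ1 (−2.45 ± 0.21), CA12 (−2.39 ± 0.17) and TPD52L1 (−2.06 ± 0.39) among them (list adjusted p = 1.23e-13, adjusted p = 0.226 with an estimated correlation). The AP-1 and stress list was lower (adjusted p = 0.0199, adjusted p = 0.477 with an estimated correlation) with 1 of 18 genes called, IER3 (−4.18 ± 0.61; 1 adjusted over the list alone), and the interferon list was higher (adjusted p = 0.0114, adjusted p = 0.477 with an estimated correlation) with 0 of 8 genes called (0 adjusted over the list alone). Neither passed with gene ends within 20 kb (0.645 and 0.0591) or without GDC-9545 replicate 1 (0.0922 and 0.113), while the luminal list passed downward within 20 kb (0.0248). The cell cycle list did not differ past the threshold (adjusted p = 0.497), and the 7 lists that did not pass had adjusted p from 0.164 to 0.958. The count of 1077 was 671 without GDC-9545 replicate 2, 613 and 578 without GNE-858 replicate 1 or 2, 394 with 10000 peaks per library, 701 on normal scores (614 lower, 87 higher) and 407 ranked by signal value. FIRRM and MYO6 lost the call without GNE-858 replicate 1 and TPD52L1 without replicate 2 (adjusted p 0.0605 to 0.141), and BAK1, AMZ1, TPD52L1 and IER3 when ranked by signal value (0.0663 to 0.209).

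The same places changed in more than 1 assay with GDC-9545. Regions are not independent replicates, and several ERα regions can overlap 1 H3K27ac region. The Fisher p-values below thus hold for these lists alone. Of 2502 ERα regions that fell and overlapped an H3K27ac region, 1122 (44.8%) had an H3K27ac region that fell, against 835 of 7927 (10.5%) ERα regions not called (odds ratio 6.91, p = 1.23e-282, two-sided Fisher's exact test across regions). With GNE-858 the figures were 185 of 1727 (10.7%) against 675 of 10880 (6.20%), an odds ratio of 1.81 (p = 7.29e-11, the same exact test). For FOXA1 with GDC-9545, 402 of 3630 ERα regions that fell (11.1%) had a FOXA1 region that fell, against 60 of 11967 (0.501%) not called, an odds ratio of 24.7 (p = 5.29e-193, the same exact test). Seen from FOXA1, 458 of the 463 regions that fell overlapped an ERα region, of which 401 (87.6%) fell, and 315 overlapped an H3K27ac region, of which 282 (89.5%) fell. By nearest gene, regions of CDH26 and GREB1, named above, fell in both FOXA1 and H3K27ac with GDC-9545, and those of SIAH2, CA12 and PGR in more than 1 of the 3 assays. A shared gene is not a shared place here, as the GREB1 regions given above by position for FOXA1 and H3K27ac do not overlap.

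**Figure D4:**
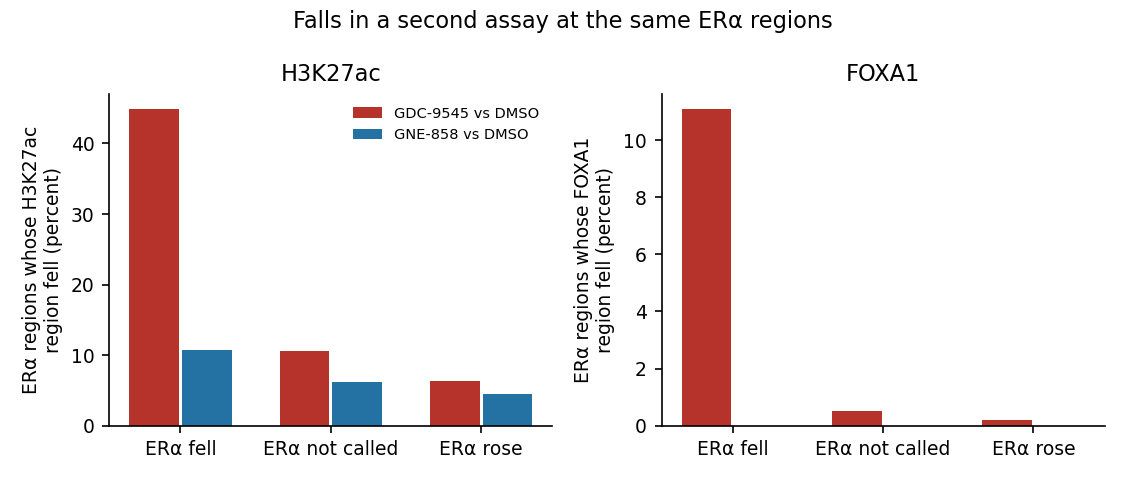
Percent of ERα regions whose overlapping H3K27ac region (left) or FOXA1 region (right) fell, by whether the ERα region fell, was not called or rose, for each compound against DMSO. The highest bars are those of ERα regions that fell with GDC-9545, at 44.8% for H3K27ac and 11.1% for FOXA1. FOXA1 bars for GNE-858 are at 0 and could not be otherwise. Only 1 FOXA1 region was called lower with GNE-858, and it overlapped no ERα region.

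The H3K27ac changes with the 2 compounds went together more than the shared DMSO libraries alone give. Of the regions called, 923 fell with both and 1454 rose with both, where independent calls would give 112.7 and 281.0. Calls in opposite directions numbered 1 and 47, where independent calls would give 164.5 and 192.5. Simulations with shared controls and no effects gave 0.02 shared calls on average, which, as for ERα, cannot show what shared controls do among many calls. The correlation across regions was 0.773, against 0.50 in the simulations, and the covariance 0.236 against 0.0329, a difference of 0.203. With a separate DMSO library for each compound, the correlation was 0.571 and 0.568 in the 2 ways to assign them, and the covariance 0.198 and 0.196. Then 453 and 394 regions fell with both compounds, where independent calls would give 42.0 and 38.7, and 397 and 613 rose with both, against 65.2 and 85.3. For FOXA1 the correlation was 0.135 against 0.499 and the covariance 0.0726 against 0.124, with correlations of 0.0298 and 0.0346 and covariances of 0.0177 and 0.0205 with separate DMSO libraries. GREB1, TFF1, STC2 and CXCL12 fell in H3K27ac with both compounds, and BIK rose with both.

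The remaining lists gave no set test past the threshold with the main settings. They were the cholesterol synthesis, aryl hydrocarbon, housekeeping, basal and mesenchymal, and other cell type lists, and their adjusted p lie in the ranges given above. As above, an upward ERα shift with gene ends within 20 kb need not be particular to a list. For ERα with GDC-9545, the housekeeping and other cell type lists passed upward with gene ends within 20 kb (0.0499 each), and the housekeeping list without GDC-9545 replicate 1 (0.0355). Between the compounds, the cholesterol synthesis list passed upward for ERα within 20 kb (0.0489) and the other cell type list without GNE-858 replicate 2 (0.0458). With GDC-9545 the strongest ERα region rose at 4 of 7 housekeeping genes and fell at 0 (4 and 0 adjusted over the list alone), and 2 of 7 cholesterol synthesis genes rose and 2 fell (2 and 2 adjusted over the list alone). Of the 17 basal and mesenchymal genes, 9 had an ERα region, of which 0 rose and 2 fell with GDC-9545 (0 and 2 adjusted over the list alone) and 0 changed with GNE-858. The same list had 4 H3K27ac regions, fewer than the 5 a test needed. Of 15 markers of other cell types, 7 had an ERα region, with 3 rising and 1 falling with GDC-9545 (3 and 1 adjusted over the list alone), and 3 had an H3K27ac region. Among lists that did not pass, the aryl hydrocarbon list for ERα between the compounds had a median over regions of −0.11 and a test direction upward, and the AP-1 and stress list for H3K27ac with GNE-858 a mean over regions of 0.15 and a test direction downward.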

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

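The tests in this part chosen after seeing the data are the crossed replicate pairing for H3K27ac, separate DMSO libraries for the compounds and leaving out libraries for the overlap between libraries. Of 247 comparison values under alternatives, 179 stayed within the bounds and 68 moved, and the cause was not tested unless stated. With 40000 peaks per library 2213 ERα regions were called for GNE-858 against 4177. On normal scores the counts for GNE-858 were 2646 for ERα, 0 for FOXA1 (limma; 7 otherwise, and 2749 at an unadjusted p below 0.05) and 1715 for H3K27ac against 2835, and 701 for H3K27ac between the compounds (614 lower and 87 higher, against 784 and 293). With 10000 peaks per library the H3K27ac counts were 2356, 1206 and 394 for GDC-9545, GNE-858 and between the compounds, and ranked by signal value 3087, 402 and 407, against 5883, 2835 and 1077. With peaks within 1000 bp joined, 13 FOXA1 regions were called for GNE-858.

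At a false discovery rate of 0.01 ERα libraries of a group shared 7.33 points more than those of different groups, against 12.2. With 40000 peaks the ERα share near a gene end with GNE-858 differed by −2.10 points, against −1.41. With the DMSO FOXA1 set throughout, the ERα sites with a FOXA1 peak differed by −6.37 points with GDC-9545 and −2.15 points with GNE-858, against −8.78 and −5.16. Lists past the threshold were 0 for ERα, 0 for FOXA1 and 0 for H3K27ac with an estimated correlation, against 4, 2 and 10, and 12 for ERα and 6 for FOXA1 with the nearest gene end within 20 kb.

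Leaving out 1 library, the ERα counts were 3456 to 13559 for GDC-9545, 20 to 9834 for GNE-858 and 6540.0 to 16934 between the compounds. For FOXA1 they were 67 to 3810.0, 0 to 8590.0 and 392 to 10747, and for H3K27ac 3889 to 5650.0, 1130.0 to 2787 and 578 to 936. The higher FOXA1 counts came without a GNE-858 library, the group with the widest spread, which enters the pooled spread. The within-group excess in shared peaks was 10.7 to 14.6 points for ERα, 1.93 to 9.72 for FOXA1 and 3.21 to 4.10 for H3K27ac. Differences near gene ends were 4.34 to 7.04 and −1.69 to −1.12 points for ERα, 0.0950 to 0.715 and −0.12 to 3.36 for FOXA1, and −2.98 to −1.16 and −2.38 to −0.560 for H3K27ac, for GDC-9545 and GNE-858. Lists past the threshold were 3 to 7 for ERα, 2 to 7 for FOXA1 and 6 to 12 for H3K27ac.

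Of 210 regions named, 6 changes turned over when peaks within 1000 bp were joined, which by construction merges neighbouring peaks into 1 region: TMOD3 for ERα with GDC-9545 (−1.05), BFSP2 (0.33), COX6C (0.62) and RASIP1 (0.0659) for ERα with GNE-858, COX6C for ERα between the compounds (−0.00862) and USP35 for FOXA1 with GNE-858 (3.92). Of 2633 values for named regions 2293 stayed on their side of the threshold, 318 no longer passed (238 of them with a library left out) and 16 newly passed. A change of sign was counted as turned over only where the main or the alternative fit passed, so the 2293 can hold others. Of 177 called regions named, 80 kept the call under every alternative run.

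The 2 libraries of a group share only a number with those of other groups. Deviations of libraries with the same number correlated at 0.0120 to 0.0191 for ERα, −0.0530 to 0.0533 for FOXA1 and −0.217 to 0.166 for H3K27ac. With the replicate number as a block, the counts were 10121, 3846 and 13263 for ERα, 526, 8 and 845 for FOXA1 and 5653, 2589 and 982 for H3K27ac, and 6 ERα and 3 FOXA1 lists passed. With the GDC-9545 numbers crossed, chosen after seeing the data, the H3K27ac counts were 6580.0, 3458 and 1213. With a separate DMSO library for each compound, which removes the covariance that shared controls give, the covariance of the changes was −0.107 for ERα (GDC-9545 with DMSO replicate 1), 0.0177 and 0.0205 for FOXA1 and 0.198 and 0.196 for H3K27ac, against −0.00284, 0.0726 and 0.236. Shares of ERα sites with an estrogen response element, with at most 1 mismatch or in a window of 50 bp, were not run, for want of a genome sequence here. Depth is unknown, so what it limits was not assessed.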

Other observations

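Tests chosen only after the result was seen are all those on the FOXA1 library that stood apart and on H3K27ac changes going together, and the values in the next paragraph were also picked then. So were the second round of ranking and the comparisons by distance to gene ends for ERα, while the other tests on ERα near gene ends were set before their results were seen.

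The ERα regions that rose with GNE-858 mostly lay outside H3K27ac regions. Of the 1978, 246 (12.4%) overlapped an H3K27ac region, against 42.4% of ERα regions not called and 78.5% of those that fell. Among these 246, H3K27ac rose at 69 (28.0%), against 14.2% beside ERα regions not called. FOXA1 regions overlapped 1093 (55.3%) of the 1978, with a median FOXA1 change of 0.60, against −0.02 at ERα regions not called. That median includes the FOXA1 library that stood apart. All 6 FOXA1 regions that rose with GNE-858 overlapped an ERα region, 3 of which rose. In GAB2 nearest USP35, ERα rose (5.30) and a FOXA1 region was called lower (−4.49, and 3.92 with peaks within 1000 bp joined). That FOXA1 region overlapped no ERα region, so these are not opposite changes at the same place.

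ERα regions that rose with GDC-9545 lay near gene ends more often than others. Rank displacement, in which sites move up because stronger ones are lost, was tested by taking out every region that fell and ranking the rest again. Of the 4356 regions, 2891 (66.4%) were still called higher, with a median change of 0.93 in place of 1.45. After that step 2667 of the regions kept were called lower. With these also taken out, 1925 (44.2%) of the 4356 were still called higher, and 48.3% of those lay near a gene end. As the whole cause, displacement had been set to leave fewer than 5% of the calls. It may account for part of the size and of the calls, and how many stays open. Background from open chromatin, which any precipitation carries, predicted a gain of more than 1 at these regions in the FOXA1 library with excess gene-end peaks. The gain was 0.340 above regions not called (bootstrap 0.307 to 0.369), between the bounds set. Among regions near gene ends alone it was 0.606 for those called higher and 0.494 for those not called, a difference of 0.112 (bootstrap 0.0432 to 0.166). Farther from gene ends it was 0.504 and 0.170, a difference of 0.334 (bootstrap 0.291 to 0.366). This background and ERα binding cannot be told apart here, since the test rests on 1 library of another antibody and no input list was used.

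FOXA1 GNE-858 replicate 1 stood apart from the other FOXA1 libraries. ERα material of the GNE-858 samples would raise its correlation with the ERα GNE-858 lists, which was lower than that of replicate 2 by a difference of −0.0219 (0.486 against 0.508). ERα material of the other samples stays open, since its mean correlation with the ERα DMSO and GDC-9545 lists was 0.549, higher by 0.104 than the highest of the other 5 FOXA1 libraries (0.445). The gap was widest with ERα GDC-9545 replicate 2, at 0.594 against at most 0.387. It was 0.537 against 0.495 and 0.543 against 0.490 with ERα DMSO replicates 1 and 2, and 0.523 against 0.436 with GDC-9545 replicate 1. ERα GDC-9545 replicate 2 also had more of its strongest peaks near a gene end than replicate 1 (14.6% against 11.9%). An exchange with another FOXA1 library of the series would give a close match elsewhere. The highest correlation of FOXA1 GNE-858 replicate 1 with any was 0.691, below the lowest among the other 5, 0.789. An exchange with a sample outside the series stays open. Its correlation with the H3K27ac lists was 0.348, higher by 0.132 than the highest of the other 5 (0.216), so a candidate explanation is more open, acetylated chromatin in that precipitate. That candidate was not separated from ERα material of the other samples, and no biological explanation was tested.

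H3K27ac fell at GREB1, TFF1, STC2 and CXCL12 with both compounds, and its changes went together across regions while those of ERα did not. The shared DMSO libraries alone gave a covariance of at most 0.0358 in 50 simulations, against 0.236. With a separate DMSO library for each compound, which removes the sharing, the covariance was 0.198 and 0.196. A fall of ERα rank at the same places would put ERα lower at H3K27ac regions that fell. With GNE-858 the median ERα change was −0.681 there and −0.483 at H3K27ac regions not called, so ERα rank was lower at both. The difference was −0.20 (−0.198, bootstrap over regions, not libraries, −0.259 to −0.126), against −1.39 with GDC-9545. The median H3K27ac fall with GNE-858 was −0.75. Of the 632 H3K27ac regions that fell with GNE-858 and had an ERα region, ERα fell at 25.8%, against 15.7% beside H3K27ac regions not called. The direction is the one such a cause needs and the size is smaller than the H3K27ac fall. A difference of at least that fall would have spoken for the cause, and an interval reaching 0 against it. The value lay between, so a fall of ERα rank and a cause apart from it cannot be told apart. A loss of ERα shared by all sites, which ranks cannot show, stays open too. With GNE-858 the ERα peaks past the false discovery rate numbered 1.33 times DMSO, higher in 4 of 4 library pairs, which runs against such a loss unless read depth, which is unknown, raised them. ERα read counts at these genes scaled by the spike-in chromatin would test it.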
